A study of Mus musculus with 4 samples.

How the data were processed

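Single-nucleus ATAC-seq marks open chromatin: a transposase inserts adapters where DNA is accessible, and the insertions are counted per nucleus. Per the labels' protocols, nuclei were isolated from flash-frozen wild-type mouse skin and libraries were made with the 10x single cell ATAC v2 chemistry. The labels give 4 libraries, 1 each from unwounded skin and from wounds at day 12, day 21 and day 28. With 1 library per group no test, p-value or standard error was computed, and no difference between groups has a replicate check.

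Per the file headers, reads were processed with Cell Ranger ATAC 2.1.0 against a mm10 reference built with its reference builder 2.0.0, and each library was run and peaks were called separately. The submitters' processing notes name Cell Ranger, Cell Ranger ATAC and mm10. The deposited peak matrices hold raw counts of transposition events per peak and nucleus, for barcodes already called as nuclei. The deposited motif matrices also hold counts, and for 746 of 746 motifs in each library they equalled the peak counts summed over the peaks that the authors' mapping assigns to the motif. The header run names read d0_lung for the unwounded library and SRF_d14 for the day 28 library, which differ from the labels. Groups were taken from the labels.

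The deposited files hold 9858 nuclei from unwounded skin, 18314 from day 12, 20007 from day 21 and 12135 from day 28, with 102952044, 63929106, 105831637 and 102547683 counts. The median count per nucleus was 9383.5, 3190, 4921 and 7779 in that order. The lowest count of any nucleus was 302 in unwounded skin, 559 at day 12, 3248 at day 21 and 567 at day 28. The day 21 library therefore holds no shallow nuclei, and why it does not is not given in the sources used here.

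Peaks of the 4 libraries were merged with bedtools 2.31.1 into 103125 regions. A region without a called peak in a library has no count in that library's matrix, so differences were measured only in the 23351 regions with a peak in every library, called shared regions here. They held 66.7% of the counts in unwounded skin, 64.0% at day 12, 65.3% at day 21 and 70.0% at day 28. Counts were expressed per 10000 counts in shared regions. A region counted as higher or lower at a 2-fold ratio with at least 100 counts over both libraries. The length that a library's peak covers in a region differs between libraries, so the ratio of counts per covered base, relative to each library's mean over shared regions, is given beside the ratios of counts of regions and genes that are called. In 8 of the 23351 regions for day 12, 15 for day 21 and 8 for day 28 the peaks of the wound library and unwounded skin do not overlap, being joined through a peak of another library, and Fbn1 at day 28 is the 1 list gene affected.

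Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes. It gives no strand. The window of a gene was therefore its span with 2000 bases on either side, in place of the planned gene body with 2000 bases upstream. A region over several genes counted for each. A gene counted as higher or lower at a 1.5-fold ratio with at least 1000 counts over both libraries, and a list member was measured with at least 100. For each of 10 gene lists, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean count. A motif counted as higher or lower when its share of the counts in shared regions differed 1.1-fold. Motifs were also grouped in 30 families. Intervals of ratios of counts are exact conditional 95% intervals, and intervals of shares are exact Clopper-Pearson 95% intervals. All of them cover counting error only, not the spread between animals. Of the non-zero matrix entries, 79.5% in unwounded skin, 84.7% at day 12, 79.7% at day 21 and 77.7% at day 28 were even. Counts therefore often came in pairs. The intervals of ratios of counts and the simulation below treat each count as independent, so both understate the counting error.

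Nuclei with at least 1000 counts, 57534 of 60314, were clustered jointly on shared regions. The steps were TF-IDF, truncated SVD with 30 components, removal of components correlated over 0.5 with log depth, a graph of 15 nearest neighbours and Leiden clustering at resolution 0.5 with seed 0. The versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The 8 clusters were named from markers chosen before the data were examined, pooled into broad classes. A name went to the class with the highest fraction of its detected markers at least 1.5-fold higher than in the other clusters, with at least 3 such markers, unless another class with at least 3 had more than 0.5 of that fraction or more markers among the 10 leading genes. This scoring rule was adjusted 3 times after the clusters were seen.

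Of the 8 clusters, 4 were epithelial-like, 1 was fibroblast-like with 7 of 10 fibroblast markers high, and 1 was leukocyte-like with 11 of 31. The fibroblast-like cluster also had 4 of 14 endothelial markers high. Within the epithelial-like class, 1 cluster was keratinocyte-like, with 6 of 13 keratinocyte and no follicle markers high, and 1 was hair-follicle-like, with 4 of 11 follicle and no keratinocyte markers high. The remaining epithelial-like clusters also had 4 of 11 follicle markers high each, with 3 and 4 of 13 keratinocyte markers high. The largest cluster, 21592 nuclei, stayed unnamed because 8 of 14 endothelial markers were high in it and mural markers, with 3 of 8, had more than 0.5 of that fraction. It is called diffuse here. Another unnamed cluster of 1512 nuclei had 7 of 8 adipocyte and 7 of 8 muscle markers high. No doublet caller was run, and an alternative left out the 5% deepest nuclei of each library.

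Named genes followed a rule set before the data were examined: members of the gene lists, and in each comparison with unwounded skin the 10 highest and 10 lowest protein-coding genes with at least 1000 counts and 2 shared regions, in all nuclei and in fibroblast-like nuclei. The same held for the 10 highest and lowest motifs and the 3 highest and lowest regions with at least 1000 counts. The calling was tested on simulated data for each comparison with unwounded skin, with 200 changed genes among 12460 at day 12, 12472 at day 21 and 12472 at day 28. All 50 genes changed 2-fold and all 50 changed 3-fold were called in each. Of the 50 changed 1.5-fold, which is the threshold itself, 27 were called at day 12, 28 at day 21 and 25 at day 28, and no unchanged gene was called. The simulation held counting noise alone, so with this count minimum few such calls were possible, and it says nothing of the spread between animals.

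Alternatives covered the scaling, the count minimum, the regions used, the gene window, the fold threshold, the nuclei included, the cluster resolution, thinning to 1500 counts per nucleus and centring per library. Of these, 29 were planned and 17 were added after the data were seen. A promoter-only window, distance from the gene start and a GC-matched background need strand or sequence, which were not used here.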

Results

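Chromatin accessibility was measured in single nuclei from the skin of wild-type mice, in 1 library from unwounded skin and 1 library each from wounds at day 12, day 21 and day 28. The series concerns retinoic acid, a signalling molecule made from vitamin A, in scarring and regenerating skin repair. Its design text also names expression and spatial measurements and an inhibitor of Cyp26b1, which are not used here. The libraries held 9858, 18314, 20007 and 12135 nuclei with 102952044, 63929106, 105831637 and 102547683 counts, in the order unwounded, day 12, day 21 and day 28. The comparisons ask which regions, genes, motifs and cell classes differed between each wound library and unwounded skin, and between successive wound days. Header run names disagree with the labels for the unwounded and day 28 libraries, so each group name below stands for the library with that label. No difference below has a replicate check, and intervals are 95% intervals for counting error only. Those of ratios of counts are too narrow even for that, because counts often came in pairs.

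The day 28 library shared the most peaks with unwounded skin. Of its 44872 peaks, 76.6% (interval 76.2 to 77.0%) overlapped a peak of the unwounded library by at least 1 base. The figure was 52.6% of 63143 peaks at day 12 (52.2 to 53%) and 43.6% of 65962 at day 21 (43.2 to 44.0%). These shares depend on how many peaks each wound library has. Of the 47810 regions called in unwounded skin, 71.1% were also called at day 28, 69.0% at day 12 and 59.6% at day 21. Counted that way, day 12 and day 28 lay close together. Called peaks covered 41.4 Mb in unwounded skin, 58.2 Mb at day 12, 55.7 Mb at day 21 and 38.1 Mb at day 28, with 2489, 1098, 1901 and 2694 counts per kb. Of the 103125 merged regions, 44037 (42.7%) were called in 1 library and 23351 (22.6%) in all 4. Restricting day 12 to peaks with at least 500 counts moved its overlap to 73.6%.

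Hair-follicle-like nuclei made up 24.9% of nuclei at day 28 (interval 24.2 to 25.7%, 2922 nuclei), against 9.71% in unwounded skin (9.12 to 10.3%, 898 nuclei), a ratio of 2.57 (2.39 to 2.75). The cluster was led by Krt25 and Krt28, keratins of the inner root sheath, and by Msx2, Dlx3 and Lef1, regulators of hair formation. Its share was 6.63% at day 12 and 7.95% at day 21, ratios of 0.683 and 0.818 to unwounded skin. The epithelial-like clusters with both keratinocyte and follicle markers high had as many follicle markers high, 4 of 11 each. The hair-follicle-like cluster therefore need not hold all follicle nuclei. From unwounded skin to day 21, 1 of those clusters went from 6.13% to 10.4% and the other from 18.4% to 9.97%. Fibroblast-like nuclei, led by the collagen gene Col1a2, were most frequent at day 21, at 14% (13.5 to 14.5%) against 9.26% in unwounded skin (8.67 to 9.87%), a ratio of 1.51 (1.40 to 1.62). Their share was 8.02% at day 12 and 9.74% at day 28.

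Leukocyte-like nuclei, with Cd74 and Lcp1 among the leading genes, made up 10.9% in unwounded skin, 10.4% at day 12, 5.30% at day 21 and 2.51% at day 28. The day 28 ratio to unwounded skin was 0.230 (interval 0.202 to 0.261). Leukocyte-like nuclei had the lowest median count of the named clusters, 4304 where the other named ones had 5363 to 8026. The day 21 library held no nucleus with fewer than 3248 counts. No alternative set that floor in every library, so its part in the day 21 share of any class was not tested. Keratinocyte-like nuclei were 16.4% in unwounded skin, 9.45% at day 12, 6.90% at day 21 and 7.16% at day 28. All 4 epithelial-like clusters together held 50.6%, 33.7%, 35.2% and 58.9% of nuclei in the same order. The 2 epithelial-like clusters with both keratinocyte and follicle markers high held 18.4%, 11.7%, 9.97% and 13.1%, and 6.13%, 5.97%, 10.4% and 13.8%. The diffuse cluster, which could not be given a cell type, held 27.4%, 46.4%, 41.2% and 26.8%. It had the lowest median count per nucleus of all clusters, 3875 where the others had 4304 to 8026. Its share was largest in the libraries with the lowest median counts per nucleus, day 12 at 3190 and day 21 at 4921. A larger diffuse cluster lowers every other share. With each nucleus thinned to 1500 counts, 1 cluster of 14651 held nuclei of both the diffuse and the fibroblast-like clusters. It held 2104 of 8547 thinned nuclei in unwounded skin, 2740 of 11164 at day 12, 7622 of 20007 at day 21 and 2185 of 10563 at day 28. Thinning merged both clusters and left out 7150 day 12 nuclei, so how far depth made the diffuse cluster cannot be told from it. The cluster with both adipocyte and muscle markers held 1.85%, 1.38%, 4.36% and 2.04%. Outside the diffuse cluster the fibroblast-like share was higher at day 12 than in unwounded skin, 15% against 12.7%, as was the leukocyte-like share, 19.5% against 15%, and the hair-follicle-like ratio at day 21 was 1.01. With each nucleus thinned to 1500 counts, the ratio at day 12 was 0.975 for keratinocyte-like and 1.01 for all epithelial-like nuclei.

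**Figure D1:**
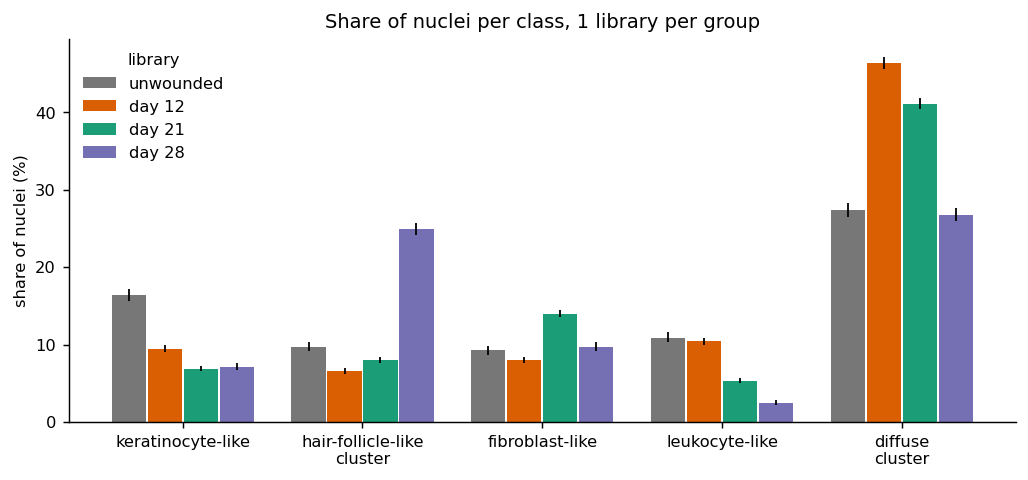
Share of nuclei (%) in 4 named groups and the diffuse cluster, 1 bar per library, with exact 95% binomial intervals for counting error. The hair-follicle-like cluster stands at 24.9% at day 28 and at 9.71% or less in the other libraries, and the diffuse cluster at 46.4% at day 12 and 41.2% at day 21.

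Among retinoid genes, Rdh10, which encodes the retinol dehydrogenase that starts retinoic acid synthesis, had more counts at day 12 and day 21 than in unwounded skin. Its ratio was 2.43 at day 12 (interval 2.30 to 2.56), 2.97 at day 21 (2.84 to 3.12) and 1.02 at day 28 (0.966 to 1.08). The Rdh10 peak at the low-coordinate end of the gene span on chromosome 1 covered 661 bases in unwounded skin (16105638 to 16106298), 1483 at day 12 (16105019 to 16106501), 1715 at day 21 (16104586 to 16106300) and 680 at day 28 (16105609 to 16106288). Per covered base the Rdh10 ratios were 1.16, 1.15 and 0.987. Crabp1, a cellular retinoic acid-binding protein, was higher at day 12, at 1.55 (1.40 to 1.71; 1.36 per covered base), and at day 21, at 1.52 (1.40 to 1.66; 1.56 per covered base), and stood at 1.01 at day 28.

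Of the 29 members of the retinoid synthesis and signalling list, 26 had a called peak in at least 1 library and 14 were measured in shared regions. At day 12 and day 21, 2 were higher, Rdh10 and Crabp1, and none lower. At day 28 none passed 1.5-fold. The list's median log2 ratio was 0.00 at day 12 (percentile 62.6 among random lists), -0.01 at day 21 (percentile 65.6) and 0.05 at day 28 (percentile 81.6). It was -0.17 at day 12 and -0.42 at day 21 with each library's own peaks. Members had peaks for 23 genes in unwounded skin, 24 at day 12, 18 at day 21 and 24 at day 28. Over the genome, 579 regions with a mean of at least 0.3 counts per 10000 in the other libraries had no called peak at day 21, against 40 for unwounded skin, 58 for day 12 and 26 for day 28. Cyp26b1, an enzyme that degrades retinoic acid, had a called peak within its span only at day 12 (chromosome 6, 84587351 to 84588303, 1243 counts) and day 28 (84587371 to 84588236, 1583 counts). No ratio can be given for Cyp26b1 because a library without a called peak has no count there.

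**Figure D2:**
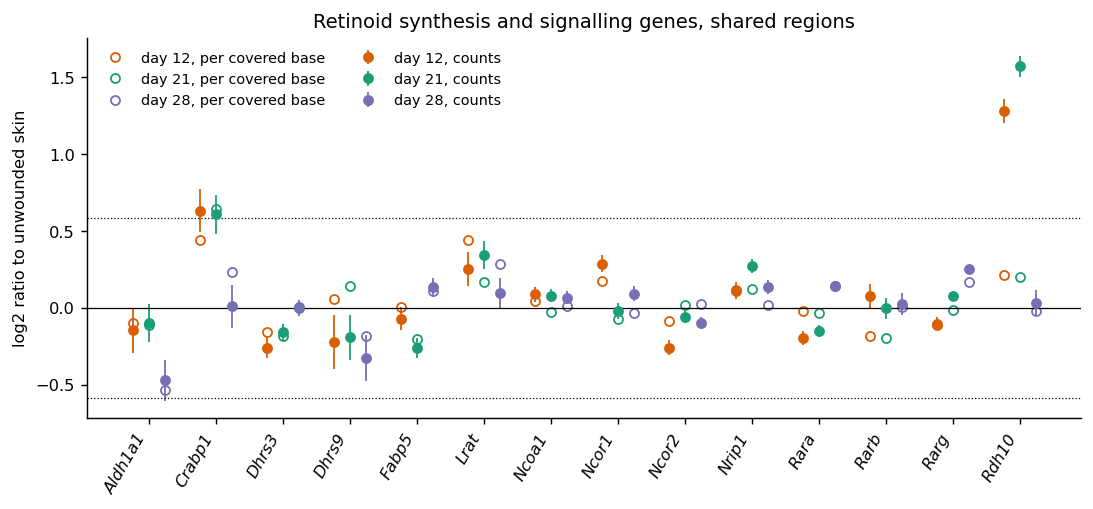
Log2 ratio to unwounded skin for the 14 retinoid genes measured in shared regions, with filled points for counts (bars, 95% counting intervals) and open points for counts per covered base, and dotted lines at the 1.5-fold threshold. Rdh10 at day 12 and day 21 lies far above the line by counts (ratios 2.43 and 2.97) and below it per covered base (1.16 and 1.15), and Crabp1 lies above the line by counts at both days.

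**Figure D3:**
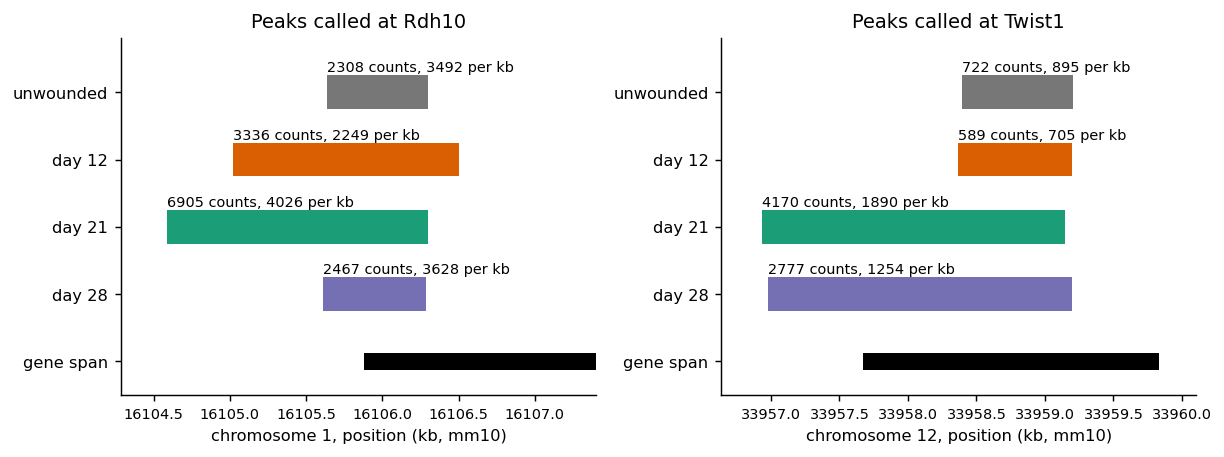
Extent of the called peaks at Rdh10 (chromosome 1) and Twist1 (chromosome 12), in kb of mm10, with the counts and counts per kb of each library printed above its bar and the gene span in black. At Twist1 the peak covers 2206 bases at day 21 and 2214 at day 28, against 807 in unwounded skin.

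At day 12, genes higher than in unwounded skin outnumbered lower ones, with 274 higher and 32 lower at 1.5-fold among 12458 genes. Among genes with at least 2 shared regions, Cpeb2, which regulates translation, stood at 2.13 (interval 2.07 to 2.20) over 3948 against 1727 covered bases, or 0.998 per covered base. Fam131b stood at 2.05 (1.29 per covered base) and the zinc finger gene Zfp993 at 1.62 (1.56 to 1.69; 1.51 per covered base). Zfp993 was among the genes that led the diffuse cluster, which held 46.4% of nuclei at day 12 and 27.4% in unwounded skin, and stood at 1.36 without that cluster. Among the lowest, Wwc2, a regulator of Hippo signalling, stood at 0.466 (0.443 to 0.490; 0.765 per covered base) and Tmprss11f, an epithelial protease gene, at 0.634 (0.597 to 0.674; 0.663 per covered base), where keratinocyte-like nuclei were 9.45% against 16.4%.

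Among extracellular matrix genes at day 12, 3 of 17 measured members were higher and none lower. These were Col1a2 at 1.61 (1.3 per covered base), the fibrillar collagen gene Col5a1 at 2.0 (1.20) and Fbn1, which encodes the microfibril protein fibrillin-1, at 2.05 (1.40). The list's median log2 ratio was 0.19 (percentile 90.7). Of 18 Wnt pathway genes, the Wnt modulators Sfrp4 at 1.58 (1.45 per covered base) and Nkd1 at 1.65 (1.3) were higher, with a median of 0.10 (percentile 96.5). Of 24 genes of hedgehog signalling and hair follicle formation, Foxd1 at 1.53 (1.46 per covered base) and Zfp423 at 1.61 (1.87) were higher and Msx1 at 0.619 was lower (1.31 per covered base), with a median of 0.06 (percentile 94.7). Nfkbia, an inhibitor of NF-kB, was the 1 lower gene of 16 interferon and inflammatory genes, at 0.616 (1.01 per covered base), and the median was 0.02 (percentile 68.9). No member passed 1.5-fold among 15 myofibroblast genes (median 0.04, percentile 94.2), 23 TGF-beta and BMP genes (-0.01, 77.9), 12 glycolysis and hypoxia genes (-0.10, 14.7), 12 proliferation genes (-0.17, 0.37) and 6 wound epidermis genes (0.08, 80.8). With each library's own peaks the hedgehog median was -0.07 and the myofibroblast median -0.05, and with clusters weighted to their unwounded shares the Wnt median was -0.01.

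Of the 23351 shared regions, 123 were at least 2-fold higher at day 12 and 34 lower. The region at Sall3, a zinc finger transcription factor gene, had the highest ratio among regions with at least 1000 counts (chromosome 18, 80985462 to 80988437), at 6.56 (interval 6.02 to 7.15) over 2976 against 601 covered bases, or 1.42 per covered base. A region within the Ttc39c window (chromosome 18, 12618192 to 12620207) was among the lowest, at 0.256 (0.226 to 0.290) and 0.222 per covered base. The 123 higher regions had a median covered length of 1468 bases at day 12 and 743 in unwounded skin, and a median ratio of 2.32 by counts and 1.31 per covered base. Per covered base, 3 regions were higher and 1 lower, and 67 genes were higher and 11 lower. Without the diffuse cluster, 160 genes were higher and 38 lower, and with clusters weighted to their unwounded shares 126 and 30.

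At day 21, genes of the extracellular matrix were higher than in unwounded skin in 7 of 17 measured members, and none was lower. Col1a2 stood at 2.19 (interval 2.03 to 2.36; 1.84 per covered base), Fbn1 at 1.76 (1.63 to 1.90; 1.88), the fibronectin gene Fn1 at 1.56 (1.47 to 1.67; 1.49), Mmp14, a matrix protease, at 1.60 (1.5 to 1.70; 1.58), and Adamts2, a procollagen peptidase, at 1.69 (1.76). The others were Loxl2 at 1.59 (1.71) and Col5a1 at 1.82 (1.45). The list's median log2 ratio was 0.35 (percentile 99.6). Fibroblast-like nuclei were also more frequent at day 21, at 14% against 9.26%, and within them 1 of 17 members, Col1a2, was higher (median 0.07, percentile 91.7). Within keratinocyte-like nuclei 6 were higher and 1 lower (median 0.30, percentile 83.7). Within epithelial-like nuclei, chosen after their values were seen, 4 were higher and none lower (0.49, 99.9). Whether nuclei of other types were counted in these classes was not tested.

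The transcription factor gene Twist1, active in mesenchyme, had a day 21 ratio of 5.74 (interval 5.30 to 6.22) in its region (chromosome 12, 33956937 to 33959203), which covered 2206 against 807 bases, or 2.1 per covered base. Foxd1 at 1.60 (1.45 per covered base) and Zfp423 at 1.56 (2.19) were the other higher members of 24 hedgehog and follicle genes, with a median log2 ratio of 0.10 (percentile 99.9). Of 18 Wnt genes, Lef1 at 1.54 (1.41 per covered base) and Nkd1 at 1.53 (1.15) were higher, with a median of 0.17 (percentile 99.6). Of 15 myofibroblast genes, Myl9, a myosin light chain gene, at 1.56 (1.60) and Ccn2, a matricellular factor gene, at 1.52 (1.35) were higher, with a median of 0.10 (percentile 99.6). None passed 1.5-fold among TGF-beta and BMP genes (median 0.00, percentile 92.5), interferon and inflammatory genes (-0.04, 56.1), glycolysis and hypoxia genes (-0.17, 3.18), proliferation genes (-0.18, 5.34) and wound epidermis genes (0.13, 89.4). With each library's own peaks the medians of the myofibroblast, Wnt, hedgehog and wound epidermis lists were below 0, at -0.17, -0.19, -0.12 and -0.25, and with clusters weighted to their unwounded shares the hedgehog median was -0.08.

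At day 21, 325 of 12474 genes were higher than in unwounded skin and 80 lower. Asmt, which encodes the last enzyme of melatonin synthesis (chromosome X, 170672644 to 170678054), stood at 2.1 (interval 2.02 to 2.18) with equal ratio per covered base, over 1942 against 1941 bases. The homeobox gene Duxf3 (chromosome 10, 58229505 to 58233089) stood at 2.08 (1.94 per covered base). At cluster resolution 0.3, Duxf3 was among the genes that led the diffuse cluster. In the main clustering the diffuse cluster held 41.2% of nuclei at day 21 and 27.4% in unwounded skin. Among the lowest genes were Tmprss11f at 0.584 (0.554 to 0.615; 0.630), Spink5, which encodes an epidermal protease inhibitor, at 0.638 (0.612 to 0.665; 0.718), and Pof1b, an epithelial actin-binding protein gene, at 0.646 (0.633). Keratinocyte-like nuclei were 6.90% at day 21 against 16.4% in unwounded skin, and epithelial-like nuclei 35.2% against 50.6%. Of shared regions, 173 were higher and 80 lower. Per covered base 53 regions were higher and 7 lower, and 199 genes were higher and 27 lower. With each nucleus weighted equally, 64 regions were higher and 70 lower. With clusters weighted to their unwounded shares 131 genes were higher and 68 lower, and with each library's own peaks 2416 and 2632.

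At day 28, Dlx3, a homeobox regulator of hair and skin differentiation (chromosome 11, 95120117 to 95125296), was higher than in unwounded skin, at 1.62 (interval 1.57 to 1.67) by counts and per covered base, with 10682 against 6324 counts. Dlx3 is among the genes that led the hair-follicle-like cluster, whose share was 24.9% at day 28 and 9.71% in unwounded skin. Twist1 stood at 3.68 (3.39 to 4.0; 1.33 per covered base), and both were the higher members of 24 hedgehog and follicle genes, with a median log2 ratio of 0.16 (percentile 100). Of 16 interferon and inflammatory genes the chemokine gene Ccl2 was lower, at 0.662 (0.632 per covered base). The median of that list was -0.23, below all 10000 random lists, in the library with 2.51% leukocyte-like nuclei against 10.9%. The median was also below 0 within fibroblast-like nuclei (-0.13, percentile 2.08) and keratinocyte-like nuclei (-0.13, percentile 1.77), and within epithelial-like (-0.17, percentile 0.14) and leukocyte-like nuclei (-0.17, percentile 1.64), both chosen after their values were seen. With clusters weighted to their unwounded shares the median over all nuclei was -0.0019 (percentile 35.5).

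Among extracellular matrix genes at day 28, Fbn1 was lower, at 0.442 (interval 0.397 to 0.492; 0.484 per covered base), and Col5a1 was higher, at 2.47 (1.14 per covered base). The Fbn1 peak at the high-coordinate end of the gene span on chromosome 2 lay at 125504578 to 125505395 at day 28 and at 125505670 to 125506571 in unwounded skin, so these peaks did not overlap and the ratio compares neighbouring stretches. The list's median log2 ratio was 0.06 (percentile 93.0). Lamb3, which encodes a laminin chain of the basement membrane, was the 1 higher gene of 6 wound epidermis genes, at 1.70 (0.865 per covered base; median 0.05, percentile 81.5). No member passed 1.5-fold among Wnt genes (median 0.08, percentile 97.9), myofibroblast genes (0.07, 93.9), TGF-beta and BMP genes (0.04, 80.8), glycolysis and hypoxia genes (-0.09, 0.90) and proliferation genes (-0.03, 33.4). The medians of the glycolysis and proliferation lists were 0.03 and 0.07 with each library's own peaks.

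Across the genome at day 28, 86 of 12467 genes were higher and 79 lower than in unwounded skin, and 44 shared regions were higher and 53 lower. Mid1, a ubiquitin ligase gene (chromosome X, 169685199 to 169990798), was among the lowest, at 0.478 (interval 0.464 to 0.493) over 5 regions and 0.480 per covered base. Ifi27 and Ifi27l2a, neighbouring interferon-induced genes that share their regions, stood at 0.626 (0.599 to 0.655; 0.640 per covered base). The Sall3 region stood at 3.82 (1.28 per covered base), and the Cflar region (chromosome 1, 58751902 to 58753066) at 0.227 (0.583 per covered base). Per covered base 31 genes were higher and 46 lower, and 6 regions were higher and 11 lower.

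**Figure D4:**
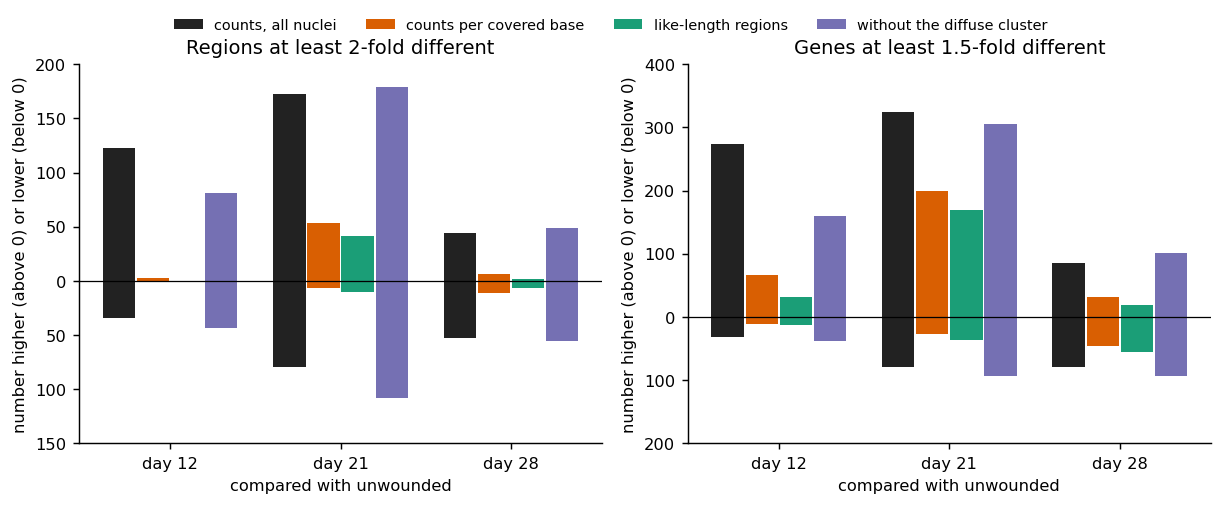
Number of shared regions at least 2-fold (left) and genes at least 1.5-fold (right) higher (above 0) or lower (below 0) than in unwounded skin at each wound day, 1 bar per way of counting. At day 12 the 123 higher regions by counts compare with 3 per covered base and 0 in regions of like length, and at day 21 the 325 higher genes by counts compare with 199 per covered base and 169 in regions of like length.

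Between day 12 and day 21, Twist1 was higher at day 21, at 4.19 (interval 3.84 to 4.58) and 1.48 per covered base, and Nfkbia was higher, at 1.60 (0.863 per covered base). Sfrp1, a secreted Wnt antagonist, was lower, at 0.622 (0.581 to 0.665; 0.893 per covered base). No extracellular matrix gene passed 1.5-fold, and the list's median log2 ratio was 0.12 (percentile 99.6). In the other lists the median was 0.04 for retinoid genes (percentile 91.8), 0.09 for Wnt (99.7), 0.04 for myofibroblast (95.3), 0.00 for hedgehog and follicle (80.8), -0.02 for TGF-beta and BMP (54.0), -0.03 for interferon (45.2), -0.05 for glycolysis (35.9), -0.05 for proliferation (47.4) and 0.02 for wound epidermis genes (76.7). With each library's own peaks the medians of the Wnt, retinoid, myofibroblast and wound epidermis lists were below 0, at -0.11, -0.22, -0.08 and -0.20, and the interferon median was 0.09. In all, 40 of 12469 genes were higher at day 21 and 81 lower, and 30 regions were higher and 63 lower. Per covered base 9 genes were higher and 3 lower, and 4 regions were higher and 1 lower.

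Between day 21 and day 28, 3 of 17 measured matrix genes were lower at the later day and none higher. Col1a2 was at 0.641 (0.599 to 0.685; 0.715) and Loxl2, a collagen cross-linking enzyme gene, at 0.627 (0.568 to 0.691; 0.705). The remaining 1, Fbn1, was at 0.251, but its called peaks at both days do not overlap. That ratio compares neighbouring stretches and is given without one per covered base. The matrix list's median log2 ratio was -0.29 (percentile 1.09), and with each library's own peaks it was 0.31. Fibroblast-like nuclei made up 14% at day 21 and 9.74% at day 28, and within them 1 matrix gene was higher and 2 lower, with a median of 0.05 (percentile 69.8). Within keratinocyte-like nuclei 0 of 13 were higher and 4 lower (0.01, 79.6). In the classes chosen after their values were seen, 1 of 17 was higher and 1 lower in epithelial-like nuclei (-0.25, 1.84), and 1 of 6 higher and 4 lower in leukocyte-like nuclei (-0.95, 0.01). Rdh10 at 0.344 (0.860 per covered base) and Crabp1 at 0.661 (0.751) were the lower retinoid genes, with a median of -0.03 (percentile 10.4), or 0.50 with each library's own peaks. Msx2 at 1.56 (1.48 to 1.64; 1.48 per covered base) and Msx1 at 1.62 (0.951) were higher at day 28, and Twist1 at 0.641 (0.633) and Foxd1 at 0.663 (0.692) were lower, with a list median of 0.01 (percentile 12.1). Msx2 also led the hair-follicle-like cluster, which was more frequent at day 28.

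The remaining medians between day 21 and day 28 were 0.18 for proliferation genes (percentile 99.0), -0.10 for interferon (2.71), 0.07 for glycolysis (33.1), -0.02 for Wnt (17.5; 0.38 with each library's own peaks), 0.01 for myofibroblast (9.40), 0.00 for TGF-beta and BMP (3.67) and 0.03 for wound epidermis genes (45.7), and none of their members passed 1.5-fold. In all, 77 of 12473 genes were higher at day 28 and 227 lower, and 41 regions were higher and 124 lower. Per covered base 17 genes were higher and 137 lower, and 4 regions were higher and 22 lower.

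Within shared regions, family medians of motif shares lay between 0.899 and 1.1 in each comparison. Retinoic acid and retinoid X receptor motifs, 22 in all, had a median ratio to unwounded skin of 1.01 at day 12, 1.02 at day 21 and 1.04 at day 28, with 3, 6 and 2 motifs at least 1.1-fold higher and none lower. RARG(var.3), the highest of them at day 12, at 1.27 (interval 1.23 to 1.31), rested on 5 regions. Over the 30 families the median ratio ran from 0.954 (NF-kB) to 1.05 (GLI and ZIC) at day 12, from 0.899 (p53 family) to 1.08 (CTCF) at day 21 and from 0.923 (p53 family) to 1.05 (KLF and SP) at day 28. It ran from 0.940 (E2F) to 1.06 (NFI) between day 12 and day 21, and from 0.947 (CTCF) to 1.1 (E2F) between day 21 and day 28. With each library's own peaks the day 21 medians ran from 0.636 (GRHL and TFCP2) to 1.14 (GLI and ZIC). The next lowest were 0.678 for AP-1, 0.702 for the p53 family and 0.729 for CTCF. In that setting 241 motifs were higher and 196 lower at day 12, and 141 and 297 at day 21. In shared regions farther than 1000 bases from either gene end, 83 motifs were lower at day 12 and 202 at day 21.

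The highest motif in at least 20 regions was NKX6-3, at 1.52 at day 12 and 1.77 at day 21. A single region within a ribosomal RNA repeat (chromosome 17, 39842875 to 39846477) held 49.0% and 56.1% of the counts of NKX6-3, and without that region the ratios were 0.959 and 0.969. NFAT5 stood at 1.24 at day 12 and 1.38 at day 21, and at 1.22 and 1.34 without its top region. Of 741 motifs, 35 were higher and 13 lower at day 12, 55 and 34 at day 21, and 19 and 13 at day 28. The counts were 20 and 25 between day 12 and day 21, and 42 and 41 between day 21 and day 28. Of the 489 motifs in at least 20 regions, 9 were higher and 0 lower at day 12, 16 and 5 at day 21, and 1 and 1 at day 28.

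Within fibroblast-like nuclei, Twist1 was higher than in unwounded skin at day 21, at 5.01 (interval 4.23 to 5.97; 1.84 per covered base), and at day 28, at 5.31 (4.46 to 6.35; 1.92 per covered base). Rdh10 stood at 2.44 at day 12 (2.06 to 2.90; 1.16 per covered base) and 3.29 at day 21 (2.85 to 3.82; 1.27 per covered base). Col1a2 stood at 1.51 at day 21 (1.33 to 1.72; 1.27 per covered base) and 1.77 at day 28 (1.55 to 2.02; 1.66 per covered base). Fbn1 stood at 0.334 at day 28 (0.270 to 0.410; 0.365 per covered base), from peaks that do not overlap. Aldh1a1, a retinal dehydrogenase gene, was lower at day 12, at 0.565 (0.357 to 0.874; 0.583 per covered base), and at day 28, at 0.563 (0.539). The Wnt ligand gene Wnt3a stood at 2.24, 1.90 and 2.34 at the 3 days (1.98, 1.83 and 2.30 per covered base), and Sfrp4 was lower at day 21 and day 28, at 0.574 and 0.589 (0.741 and 0.701). Of 18 measured Wnt genes in this class, 2 were higher and 0 lower at day 12, 3 and 2 at day 21, and 1 and 1 at day 28.

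The retinoid list in fibroblast-like nuclei had a median log2 ratio of -0.09 at day 12 (percentile 9.27), 0.08 at day 21 (percentile 94.5) and 0.02 at day 28 (percentile 60.9). The matrix list had 0 higher and 2 lower members at day 12, 1 and 0 at day 21, and 2 and 1 at day 28, with medians of 0.04, 0.07 and -0.06 (percentiles 61.5, 91.7 and 26.6). Among genes outside the lists, Sorl1, a sorting receptor gene, stood at 1.92 at day 21 (1.98 per covered base) and Dsp, the desmoplakin gene, at 1.81 (1.72). Mid1 stood at 0.524 at day 28 (0.526 per covered base). Of 6 wound epidermis genes, 2 were higher in this class at day 21, Lamb3 at 2.45 (1.57 per covered base) and the growth factor gene Ereg at 2.5 (2.61), and Dsp also encodes an epithelial junction protein. Whether epithelial nuclei were counted in this class was not tested. At 1.5-fold, 15 genes were higher and 7 lower at day 12, 34 and 33 at day 21, and 21 and 11 at day 28. The counts were 32 and 58 between day 12 and day 21, and 37 and 28 between day 21 and day 28.

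Within keratinocyte-like nuclei, Rdh10 stood at 2.52 at day 12 (interval 2.21 to 2.88; 1.20 per covered base) and 2.77 at day 21 (2.43 to 3.16; 1.07 per covered base), and Crabp1 at 1.83 and 1.78 (1.61 and 1.82 per covered base). Lrat, which encodes a retinol esterifying enzyme, was also higher at both days, at 1.74 and 1.54 (1.98 and 1.36 per covered base), and Dhrs9, a retinol dehydrogenase gene, was lower at day 12, at 0.637 (0.774). Crabp1 was the 1 member past the threshold at day 28, at 1.60 (1.87). The medians of the 14 measured retinoid genes were -0.01, -0.03 and 0.08 at the 3 days (percentiles 43.1, 45.2 and 87.8). Fn1 was higher at day 21, at 2.67 (2.04 to 3.49; 2.54 per covered base). Whether nuclei of other types were counted in the keratinocyte-like class was not tested. Ccl2 was lower at day 28, at 0.270 (0.258 per covered base), on 44 against 396 counts. At 1.5-fold, 70 genes were higher and 39 lower at day 12, 66 and 162 at day 21, and 38 and 27 at day 28. The counts were 20 and 30 between day 12 and day 21, and 38 and 20 between day 21 and day 28. Per covered base, 12 genes were higher and 28 lower at day 12, and 35 and 112 at day 21.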

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

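The tests below of peak width, of the diffuse cluster, of the follicle-like share and of the header names were all chosen after the results they bear on were seen.

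Over all nuclei, more shared regions and genes were higher than lower at day 12 and day 21, except in like-length regions at day 12 (0 and 1) and, at day 21, with each nucleus weighted equally (64 and 70 regions) or each library's own peaks (2416 and 2632 genes), but within classes fewer genes were higher than lower at day 21 in keratinocyte-like (66 and 162) and leukocyte-like nuclei (11 and 23), near gene ends in fibroblast-like nuclei (21 and 30), and per covered base at day 12 in fibroblast-like (5 and 7), keratinocyte-like (12 and 28), epithelial-like (15 and 20) and leukocyte-like nuclei (1 and 6). The wound day, peak calling per library and the mix of nuclei are candidate explanations: per covered base, the median ratio of the 123 regions higher at day 12 was 1.31 (quartiles 1.15 to 1.48) where their median ratio of counts was 2.32, and that of the 173 regions at day 21 was 1.51 (1.28 to 1.97) against 2.26. Wider called peaks may therefore account for part of both sets, but a peak that opens more widely would also be called longer, so calling and wider opening cannot be told apart without counts outside the called peaks. Without the diffuse cluster, which held 46.4% of nuclei at day 12 and 27.4% in unwounded skin, the 274 genes higher at day 12 had a median ratio of 1.53 (1.42 to 1.64) and 150 stayed at 1.5-fold, which leaves the part of that cluster open. At day 21 the 325 higher genes had a median of 1.66 (1.55 to 1.81) without it and 273 stayed, which argues against the diffuse cluster as the whole cause there, but with all clusters weighted to their unwounded shares 126 genes were higher at day 12 and 131 at day 21, so the mix of nuclei may account for part, and the wound day was not tested because each day has 1 library.

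Hair-follicle-like nuclei made up 24.9% of nuclei at day 28 and 9.71% in unwounded skin, and depth, a loss of other nuclei and the wound day are candidate explanations. With each nucleus thinned to 1500 counts the ratio was 2.56, against 2.57 before thinning, which argues against depth. The thinned cluster was larger, with 9822 nuclei against 6508, so both ratios do not rest on the same set. The share of the other epithelial-like clusters had a ratio of 0.832, at 34.0% against 40.9%, and within it 1 of the clusters with both keratinocyte and follicle markers high was also higher, at 13.8% against 6.13%, while the other such cluster, at 13.1% against 18.4%, and the keratinocyte-like one, at 7.16% against 16.4%, were lower. The fibroblast-like ratio was 1.05, so the classes moved apart, which argues against a loss of some classes that raised all others alike as the whole cause. The wound day stays open as an untested explanation, since 1 library stands for each day and the labels give neither the hair cycle stage nor the site sampled.

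The header run names read d0_lung for the unwounded library and SRF_d14 for the day 28 library, so another tissue, another day or names reused from another project are candidate explanations. Counts at 14 lung markers were 1.24 times the mean of the wound libraries in the unwounded library, and counts at 14 skin markers were also 1.24 times, at 8.61 per 10000 against 1.65 for lung. Skin markers had called peaks for 12 of 14 in the unwounded library and lung markers for 5 of 14, which argues against lung as the tissue. The day 28 library correlated at 0.968 with day 12, 0.974 with unwounded skin and 0.966 with day 21 across shared regions, and with no library labelled day 14 its day cannot be told apart from these values.

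Fbn1 had ratios to unwounded skin of 2.05 at day 12 and 0.442 at day 28, but its day 28 and unwounded peaks do not overlap, so the latter ratio compares neighbouring stretches, and the difference was not tested. In the regions that the comparisons leave out, 2550 were called in all 3 wound libraries and not in unwounded skin. Cyp26b1 had 1243 counts in its called peak at day 12 and 1583 at day 28, with no peak called in unwounded skin.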

How the results depend on the processing

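The alternatives on like-length regions, the diffuse cluster, counts per covered base, windows and distances from gene ends, and motifs in at least 20 regions were chosen after seeing the data. Of 737 values under alternatives, 458 lay near the main value (counts within 1.5 times, others within the spread of members or the counting interval), 126 moved above it, 140 moved below it and 13 reversed. Reversed is kept for list medians in the highest or lowest 2.5% of random lists and class ratios whose interval leaves out 1. A further 51 list medians and 2 class ratios with no such call also changed side. Counts of regions and genes stayed near the main ones under median-of-ratios scaling, other count minimums and leaving out the 5% deepest nuclei. The planned promoter-only window, distance from the gene start and GC-matched background were not run, because strand and sequence were not used here. No paired analysis was possible because each group has 1 library. Depth limits the results within classes: in fibroblast-like nuclei 3633 genes reached the count minimum at day 12, 7216 at day 21 and 5280 at day 28, against 12458, 12474 and 12467 in all nuclei. Where no reason is given, the cause was not tested. Pairs of counts below are higher, then lower.

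For peak sets, a reciprocal overlap of 50% gave shares of 51.8%, 43.0% and 76.1% overlapped by unwounded peaks at day 12, day 21 and day 28, and peaks with at least 500 counts gave 73.6%, 46.3% and 77.3%. For regions compared with unwounded skin, those with a peak in both libraries gave 228 and 68 at day 12 and 278 higher at day 21. At day 28 they gave 68 and 88. Between wound days they gave 96 and 150 for day 21 against day 12 and 207 lower for day 28 against day 21. Such regions numbered 33009, 28483 and 33970 against unwounded skin, then 42702 and 28594, where shared regions numbered 23351. The calls given here rose by a larger factor than the regions, so the number tested does not account for the whole rise. A 1.5-fold threshold, looser by construction, gave 780 and 267, 1312 and 646, and 245 and 493 against unwounded skin, then 180 and 213, and 229 and 1013 between wound days. With each nucleus weighted equally 64 regions were higher at day 21 than in unwounded skin, and 79 were lower at day 28 than at day 21.

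Like-length regions, 17989 of the 23351, gave 0 and 1 regions at day 12, 41 and 10 at day 21 and 2 and 7 at day 28 against unwounded skin, then 1 and 0, and 1 and 22 between wound days. Genes gave 31 and 13, 169 and 36, and 19 higher, then 10 and 0, and 11 and 124. Motifs gave 21 higher at day 12, 14 lower for day 21 against day 12 and 25 higher for day 28 against day 21. Counts per covered base gave 3 and 1 regions at day 12, 53 and 7 at day 21 and 6 and 11 at day 28, then 4 and 1, and 4 and 22. Genes gave 67 and 11, 199 and 27, and 31 and 46, then 9 and 3, and 17 and 137. Within fibroblast-like nuclei it gave 5 higher at day 12, 7 and 7 at day 28, 29 lower for day 21 against day 12 and 17 lower for day 28 against day 21. Within keratinocyte-like nuclei it gave 12 higher at day 12, 35 higher at day 21, 7 and 14 at day 28, then 7 lower, and 20 and 12. By construction, like-length regions let called lengths differ by at most 25% and counts per covered base divide by the length.

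Without the diffuse cluster, 81 regions and 160 genes were higher at day 12 than in unwounded skin, 77 genes were higher at day 21 than at day 12 and 27 motifs higher at day 28 than at day 21. With clusters weighted to their shares in unwounded skin, 126 genes were higher at day 12, 131 higher at day 21, 55 and 26 at day 28, and 87 lower for day 28 against day 21. That weighting gave 17 motifs lower at day 21 and 21 higher for day 28 against day 21. It turned the day 21 median of hedgehog and follicle genes to -0.076 from 0.10 and the day 28 median of glycolysis genes to 0.0032 from -0.09.

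With each library's own peaks, genes gave 1736 and 1672 at day 12, 2416 and 2632 at day 21 and 1284 and 1191 at day 28, then 1321 and 1834, and 2775 and 2353. Motifs gave 241 and 196, 141 and 297, and 230 and 154, then 95 and 327, and 337 and 127. These counts include which peaks were called. The retinoid list's median was -0.17 at day 12 and -0.42 at day 21, and the day 28 median ratio of retinoid receptor motifs was 1.14. The median reversed to -0.17 from 0.10 for myofibroblast genes at day 21, to -0.19 from 0.17 for Wnt genes at day 21, to -0.11 from 0.09 for Wnt genes in day 21 against day 12, to -0.12 from 0.10 for hedgehog and follicle genes at day 21, to 0.032 from -0.09 for glycolysis genes at day 28, and to 0.31 from -0.29 for matrix genes in day 28 against day 21.

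Regions within 1000 bases of either gene end gave 20 genes lower at day 12 and retinoid list medians of 0.21 at day 12 and 0.24 at day 21. Fibroblast-like nuclei then gave 21 and 30 at day 21, where the main counts were 34 and 33, and 13 higher for day 21 against day 12, and keratinocyte-like nuclei 13 higher for day 21 against day 12 and 11 lower for day 28 against day 21. Regions farther than 1000 bases gave motifs of 83 lower at day 12, 202 lower at day 21 and 61 and 32 at day 28, then 31 and 75, and 257 higher for day 28 against day 21. Motifs in at least 20 shared regions gave 9 and 0, 16 and 5, and 1 and 1, then 5 and 2, and 8 and 16, with fewer motifs tested.

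For class shares, ratios to unwounded skin at day 28 kept their direction in every clustering that gave one. Over nuclei outside the diffuse cluster, day 12 and day 21 ratios were 1.17 (reversed) and 1.86 for fibroblast-like, 1.30 (from 0.956) and 0.600 for leukocyte-like, 0.925 and 1.01 (reversed) for hair-follicle-like and 0.781 and 0.519 for keratinocyte-like nuclei. No minimum per nucleus gave 1.76 for fibroblast-like, 0.539 for leukocyte-like and 0.737 for hair-follicle-like nuclei at day 21, and 0.501 for keratinocyte-like nuclei at day 28. Leaving out the 5% deepest nuclei gave 1.39 for fibroblast-like nuclei at day 21. Resolution 1 gave 0.532 for leukocyte-like and 1.00 (reversed from 0.818, lying just above 1) for hair-follicle-like nuclei at day 21. It gave 0.712 and 0.575 for keratinocyte-like nuclei at day 12 and day 21. Resolution 0.3 gave 0.70 for hair-follicle-like nuclei at day 21, and 0.530 and 0.333 for keratinocyte-like nuclei at day 12 and day 21. Thinning gave 0.552 for leukocyte-like nuclei at day 21, 0.979 and 1.18 (reversed) for hair-follicle-like and 0.975 and 0.547 for keratinocyte-like nuclei at day 12 and day 21, and 1.01 (reversed) for epithelial-like nuclei at day 12. It left out 1311, 7150, 0 and 1572 nuclei in library order. Thinning gave no fibroblast-like value, because those nuclei shared 1 cluster of 14651 with nuclei of the diffuse cluster. That cluster had 8 of 10 fibroblast markers high. The thinned hair-follicle-like cluster held 9822 nuclei, against 6508 in the main clustering, so its ratios rest on another set of nuclei. Centring per library gave 0.552 and 0.263 for leukocyte-like nuclei at day 21 and day 28, 0.750, 0.954 and 2.21 for hair-follicle-like and 0.650, 0.535 and 0.487 for keratinocyte-like nuclei at the 3 days.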

Other observations

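The features in this part were chosen after their values were seen. Among the 2550 regions called in all 3 wound libraries and not in unwounded skin were regions in the windows of Rarb, a retinoic acid receptor gene, and of Nrip1, a nuclear receptor co-repressor gene. Of the Wnt list 5 of 34 members had such a region (Wnt3a, Wnt5a, Lef1, Tcf7l1 and Lgr6), and of the hedgehog and follicle list 6 of 35 (Ptch1, Gli3, Hhip, Sox18, Prdm1 and Corin). The matrix list had 3 of 36 (Col5a1, Col12a1 and Fbn1), the myofibroblast list 3 of the 25 members that the gene table names (Cnn1, Tpm1 and Piezo1) and the TGF-beta and BMP list 1 of 26 (Bmpr1a). The interferon, glycolysis, proliferation and wound epidermis lists had 0. Of the 2550 regions, 1494 lay in the window of some protein-coding gene. The share of all genes with such a region was not computed and gene length was not matched, so these counts do not set any list apart. The strongest such region lay in the Arid2 window (chromosome 15, 96286404 to 96288345), with 0.660 counts per 10000 at day 12, 0.619 at day 21 and 0.752 at day 28, and the next in the Zc3h4 window (chromosome 7, 16400750 to 16401773), with 0.635, 0.622 and 0.652.

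Motifs of the KLF and SP family were mapped to 9.69% of these 2550 regions (interval 8.57 to 10.9%) and to 6.84% (6.32 to 7.39%) of the 8755 regions called in another set of 3 libraries. The intervals also lay apart for GATA, at 2.55% (1.97 to 3.24%) against 4.56% (4.13 to 5.02%), for CTCF, at 1.69% (1.22 to 2.26%) against 3.05% (2.70 to 3.43%), and for SOX, at 22.3% (20.7 to 24.0%) against 25.7% (24.8 to 26.6%). Retinoid receptor motifs were mapped to 1.41% (0.991 to 1.95%) and 1.06% (0.858 to 1.30%). Of the 8755 comparison regions, 4559 lacked a peak at day 21 alone. The contrasts therefore cannot be told apart from what went uncalled in the day 21 library. Peaks missing from 1 library were not particular to unwounded skin: 1387 regions were missing at day 12 alone, 4559 at day 21 alone and 2809 at day 28 alone. Of these, 58, 579 and 26 had a mean of at least 0.3 counts per 10000 in the libraries with a peak, against 40 of the 2550.

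In leukocyte-like nuclei at day 21, Sox9, a regulator of follicle stem cells, stood at 3.17 times the unwounded value (interval 2.08 to 4.92; 3.01 per covered base) and the fibroblast growth factor receptor gene Fgfr2 at 2.13 (1.76 to 2.59; 2.25 per covered base). In that class 8 of 23 measured hedgehog and follicle genes were 1.5-fold higher, and 6 of 13 matrix genes, among them Timp3 at 1.87 (1.81 per covered base) and Col1a2 at 1.82 (1.54). The medians of both lists were 0.45 and 0.52 in log2. Whether nuclei of other types were counted in this cluster was not tested.

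A ribosomal RNA repeat on chromosome 17 held 0.609% of counts in shared regions in unwounded skin, 1.22% at day 12, 1.62% at day 21 and 0.512% at day 28. A repeat on chromosome 2 held 0.948%, 1.21%, 1.37% and 0.885%. Aldh1a3, which encodes a retinal dehydrogenase, had 3 called regions in unwounded skin, 1 at day 12, 0 at day 21 and 4 at day 28. Stra6, the retinol transporter gene, had 7, 1, 3 and 6. Day 21 is the library with most regions missing from it alone, 4559, although it had the most called regions in all, 65336.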
